A study of Mus musculus with 8 samples.

How the data were processed

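RNA of CD4 T cells sorted from the spleens of male NOD mice was measured on 8 Affymetrix ST1.0 arrays, 1 per sample. The samples fell into 3 groups by the labels, with 3 arrays of Flicr-knockout Tregs, 3 of wild-type Tregs and 2 of wild-type Tconvs. The deposited values are intensity, 1 value per probe set and array, on a linear scale. Affymetrix Power Tools and RMA are named in the submitters' processing notes, with no version given. The notes do not say which steps followed RMA.

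The table held 24922 probe sets. A single probe set with a blank value was left out. Of the rest, 21425 named 1 gene, 1399 named several and 2097 listed none. Entrez numbers matched 21347 of the probe sets with 1 gene to the RefSeq table of GRCm38.p6, and 0 symbols had to be updated. That table was used for names and neighbours alone, since the build behind the array's annotation is not given in the sources used here.

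Intensities were converted to log2. Probe sets were kept when their mean over the 8 arrays was at or above the median of all probe-set means (7.27 on the log2 scale), which left 12461. Those naming exactly 1 gene were used, and a gene with several was represented by the brightest, giving 9815 genes. All 8 arrays entered a single limma fit of the 3 group means, with 5 residual degrees of freedom, in R 4.3.3 with limma 3.58.1 and statmod 1.5.0. The contrasts were Flicr-knockout minus wild-type Tregs, and wild-type Tregs minus wild-type Tconvs. Tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. Errors given with log2 differences are limma standard errors (SE), and intervals cover 95%. The number of arrays limits the precision. For Flicr and Foxp3 an exact two-sided permutation test of the 3 against 3 arrays was added, whose smallest possible p is 0.1.

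A total of 22 gene lists were written before the data were examined. They were the Treg-up signature, the Treg-down signature, Foxp3 locus neighbours, effector Treg genes, resting lymphocyte genes, the IL-2 and STAT5 response, TCR and immediate early genes, the interferon response, cell cycle, helper T cell cytokines and regulators, inhibitory and costimulatory receptors, CD4 T cell identity, cholesterol synthesis, glycolysis, heat shock and dissociation stress, and sex-linked genes as a label check. The others held markers of B cells, myeloid cells, dendritic cells, NK cells, CD8 T cells, and erythroid cells and platelets. Several lists share members. Each list was tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Members that passed over all genes, and adjusted over the list alone, were counted beside it.

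The genes to name were fixed by a rule before the data were examined. It took Flicr, Foxp3, Ppp1r3f, Ccdc22, Cacna1f and Il2ra in every comparison. It added the 10 genes per direction with the largest differences among those that passed with no overlap between samples, leaving out predicted genes, clones and receptor segments. Where fewer passed, the 5 genes per direction with the smallest unadjusted p were added as values only. From each list it took up to 4 members that passed and up to 2 that did not. Genes named outside the rule are marked as chosen after their values were seen.

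Alternatives fixed before the data were examined were no filter, a filter at the 25th percentile, every probe set past the filter, only the groups compared, an eBayes fit with trend and robust settings, renewed quantile normalization, centring of each array on its median, array weights, the replicate number as a block, looser and stricter thresholds, and leaving out each array in turn. For the lists they also included camera with an estimated correlation and limma's fry. Later additions were a stress score as a covariate (the mean of the immediate early and heat shock lists), a term for 3 Treg arrays with high immediate early scores, and both renewed scalings for the lists.

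The fit was tested on simulated data with changes of known size in 9815 genes over 5 rounds. For knockout against wild-type Tregs it recovered 18.8% of changes of 1.25-fold, 70.0% of 1.5-fold, 94.0% of 2-fold and 99.6% of 3-fold, with 4.08% false calls. For Tregs against Tconvs the shares were 12.0%, 60.4%, 90.8% and 99.2%, with 4.65% false calls. Camera called 0 of 110 unchanged lists in each contrast. The simulated genes varied independently of each other, whereas the estimated correlation was 0.47 in the Treg-up signature and 0.25 in the heat shock list. These rates therefore do not cover lists or genes whose levels vary together.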

Results

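Splenic CD4 T cells of male NOD mice, a strain that develops autoimmune diabetes, were profiled at 8 weeks of age. Regulatory T cells (Tregs), which restrain other lymphocytes, were sorted as the CD25hi cells, the top 50% by the labels. Conventional T cells (Tconvs) were sorted as CD25 negative, and cells with CD11c, CD19, CD8, CD49b or Ter119 were excluded. The arrays covered Tregs lacking the long noncoding RNA Flicr (n = 3), wild-type Tregs (n = 3) and wild-type Tconvs (n = 2), with no knockout Tconvs. Median intensity ran from 149 in wild-type Treg replicate 3 to 162 in knockout Treg replicate 2. The labels do not say whether replicates are separate animals. The p-values of single genes, of fry and of the permutation test below therefore measure only the spread between samples. Camera compares the genes of a list with all other genes, so its p also rests on the spread between genes and on the correlation used.

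The first comparison set Flicr-knockout against wild-type Tregs, for a transcript that the series title links to Foxp3 expression. Flicr intensity (probe set 10598289) was 5.41-fold lower in knockout Tregs (95% interval 4.38 to 6.68), with intensities of 99.0, 96.7 and 102 in the knockout arrays against 419, 618 and 596 in the wild-type arrays. Foxp3 (probe set 10598292), the transcription factor that defines Tregs, had log2 levels of 12.72 ± 0.074 (SD, n = 3) in knockout and 12.60 ± 0.055 (SD, n = 3) in wild-type Tregs. The Foxp3 difference was 1.09-fold, with a 95% interval of 0.959 to 1.24. Tregs of both genotypes were sorted as the top 50% by CD25, so this value does not cover Tregs outside that gate. In the RefSeq table Flicr lies between Ppp1r3f and Foxp3 and overlaps both. Ppp1r3f, which encodes a regulatory subunit of a phosphatase, had a log2 difference of 0.13 (SE 0.111), and Ccdc22, on the other side of Foxp3, one of 0.19 (SE 0.142).

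Flicr passed the test in limma with Benjamini-Hochberg adjustment (log2 difference -2.44, SE 0.139, adjusted p = 1.37e-05), and all 3 knockout arrays lay below all 3 wild-type arrays. The exact permutation test gave p = 0.1 for Flicr, the smallest that 3 against 3 arrays allow, and p = 0.2 for Foxp3. Foxp3, Ppp1r3f and Ccdc22 each had an adjusted p of 1 in limma. Cacna1f, a calcium channel gene beyond Ccdc22, was below the filter, with a log2 difference of 0.060. Il2ra, which encodes the sorted marker CD25, differed by -0.057 (SE 0.119). Flicr intensity was 82.9 and 100 in the Tconv arrays, and knockout Tregs differed from these by 0.12 on the log2 scale (95% interval -0.21 to 0.45). At that level 64.3% of probe sets were brighter and background was not measured, so the folds given for Flicr are ratios of intensity and not of transcript. The labels do not place the deleted part relative to the probe set.

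**Figure D1:**
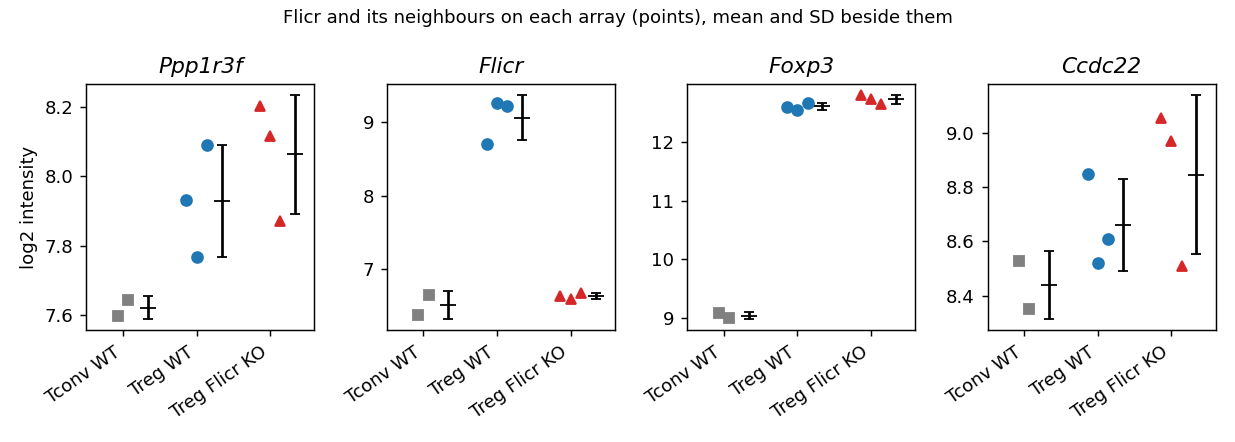
Log2 intensity of Ppp1r3f, Flicr, Foxp3 and Ccdc22 on each of the 8 arrays (points), with the mean and SD of each group beside them and a separate vertical scale for each gene. Flicr lies between 6.60 and 6.67 in the knockout Tregs and between 8.71 and 9.27 in the wild-type Tregs, while Foxp3 lies between 12.55 and 12.80 in all 6 Treg arrays.

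Flicr was the 1 gene of 9815 that passed between genotypes. The smallest unadjusted p among the others included Il7r, the receptor chain for interleukin-7 (log2 difference 0.50, adjusted p = 0.33 in limma), and Dapl1, a gene of resting lymphocytes (-0.73, adjusted p = 0.283). Slc35d1, a nucleotide-sugar transporter, Rapgef5, an exchange factor for Rap proteins, Cd80, a costimulatory ligand, and Dnaja1, a chaperone cofactor, had log2 differences of 0.52, 0.64, 0.71 and 0.46. A second probe set of Cd80 gave 0.43. Igfbp4, which binds insulin-like growth factors, Cybb, a subunit of the phagocyte oxidase, Gpm6b and Tmem97 had differences of -0.85, -0.46, -0.32 and -0.34. None of these 10 genes passed, at adjusted p from 0.283 to 1. An unadjusted p under 0.05 was found for 223 genes (2.27%), where chance gives 491 on average. That count was 970 (9.88%) without wild-type Treg replicate 1, 820 (8.36%) without knockout Treg replicate 3 and 1108 (11.3%) with array weights, and it was 134, 133 and 117 without knockout Treg replicate 2, wild-type Treg replicate 2 and wild-type Treg replicate 3. No overlap between the groups was found for 413 genes (4.21%, where chance gives 10%). The 95% interval lay within 2-fold for 99.7% of genes and within 1.5-fold for 97.2%. The count was 5 without wild-type Treg replicate 1, 2 without knockout Treg replicate 3 (Flicr and Hsph1), and 4 with array weights, where Il7r (adjusted p = 0.0411) and Dapl1 (adjusted p = 0.0404) passed beside Flicr and Cxcr4. With a term for 3 Treg arrays with high immediate early scores, added after seeing the data, it was 9, with Igfbp4, Cd80, Dapl1, Rapgef5, Il7r and Slc35d1 among them. Hsph1 and Cxcr4 were chosen after their values were seen. The array weights ran from 0.326 in wild-type Treg replicate 1 to 4.50 in wild-type Treg replicate 2. The weighted wild-type mean therefore rests mostly on replicate 2, with little from replicate 1.

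**Figure D2:**
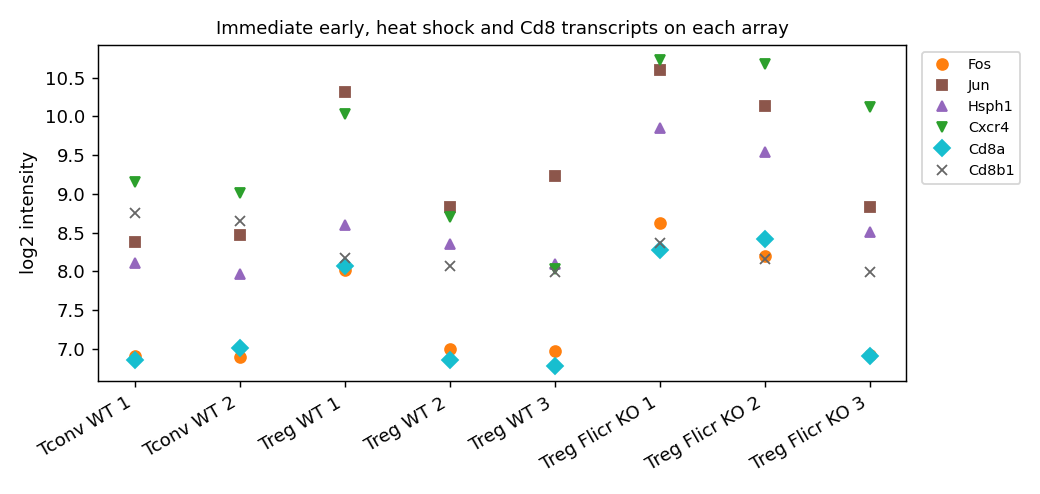
Log2 intensity of the immediate early genes Fos and Jun, the heat shock gene Hsph1, the chemokine receptor gene Cxcr4 and the CD8 chain genes Cd8a and Cd8b1 on each of the 8 arrays (1 point per gene and array). Fos ranges from 6.92 to 8.63 within the knockout Tregs and from 6.97 to 8.02 within the wild-type Tregs.

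Among the fixed lists, all 8 measured heat shock and dissociation stress genes had positive log2 differences between knockout and wild-type Tregs (7 without knockout Treg replicate 3 or wild-type Treg replicate 1), with a median of 0.33, and camera called the list upward (adjusted p = 6.45e-10). The call was lost with an estimated correlation (adjusted p = 0.196), and fry gave an adjusted p of 0.546, though fry called the list without knockout Treg replicate 3 (adjusted p = 0.0384). The list's chaperone genes Hspa8 and Hsp90aa1 differed by 0.25 (SE 0.0897) and 0.39 (SE 0.124). Of the TCR and immediate early genes, which respond within minutes to hours of stimulation, 14 of 17 had positive differences, with a median of 0.20 and a camera call upward (adjusted p = 5.24e-05). That call was lost as well (adjusted p = 0.694 with an estimated correlation, and 0.735 by fry). The median was 0.066, with 11 of 17 positive, without knockout Treg replicate 1 and 0.31 without knockout Treg replicate 3. Cd69, an early activation marker, differed by 0.17 and Cd5, an inhibitory surface protein, by -0.013. In the Treg-down signature, genes known to be lower in Tregs than in Tconvs, 10 of 15 had negative differences, with a median of -0.073 and a camera call downward (adjusted p = 0.024). It was lost with an estimated correlation (adjusted p = 0.752), by fry (0.735), and in camera without knockout Treg replicate 3 (0.196). The median of the Treg-down signature was -0.13 without knockout Treg replicate 1, -0.038 without knockout Treg replicate 2 and -0.15 without wild-type Treg replicate 1. Dapl1 (-0.73) and Igfbp4 (-0.85) lay at its lower end, and Il7r (0.50) had the opposite sign. By limma 0 members of these lists passed over all genes, while 5 heat shock genes, 1 immediate early gene and 5 Treg-down genes had an unadjusted p under 0.05. Single arrays moved these counts, to 2 and 3 heat shock genes without knockout Treg replicates 1 and 2. Immediate early genes numbered 9 without knockout Treg replicate 3, 7 without wild-type Treg replicate 1 and 0 without knockout Treg replicate 1 or wild-type Treg replicate 2, and Treg-down genes 3 without knockout Treg replicate 2, wild-type Treg replicate 2 or wild-type Treg replicate 3. Other settings let members pass, such as Hsph1 without knockout Treg replicate 3, Il7r and Dapl1 with array weights, and Il7r, Dapl1 and Igfbp4 with the term for high immediate early scores. Adjusted over the list alone, 4 heat shock genes passed, and in the Treg-down signature Il7r passed upward and Dapl1 and Igfbp4 downward. By that count 0 heat shock genes passed without knockout Treg replicate 1, knockout Treg replicate 2 or wild-type Treg replicate 3. Without knockout Treg replicate 3 it was 9 immediate early genes and 2 Treg-down genes upward, and without wild-type Treg replicate 1 it was 4 Treg-down genes downward. The mean log2 level of the immediate early list varied within genotype, at 9.87, 9.66 and 9.32 in knockout Tregs and 9.53, 9.35 and 9.38 in wild-type Tregs. That of the heat shock list was 10.54, 10.47 and 10.11 in knockout and 10.07, 9.99 and 9.89 in wild-type Tregs.

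The Treg-up signature, 31 measured genes known to be higher in Tregs, held 0 members that passed between genotypes, and its median log2 difference was -0.057 (camera adjusted p = 0.223). That median was -0.19 without wild-type Treg replicate 1 and -0.14 without knockout Treg replicate 3, and it turned to 0.0030 without knockout Treg replicate 2 and 0.017 without wild-type Treg replicate 3. Ctla4, an inhibitory receptor, differed by 0.18, Ikzf2, the Treg transcription factor Helios, by 0.043, and Il2rb, the beta chain of the interleukin-2 receptor, by 0.035. Of the 18 Foxp3 locus neighbours 1 passed, Flicr itself, and Plp2, a membrane protein gene, differed by -0.35 (camera adjusted p = 0.142). For effector Treg genes 0 of 22 passed (0.256), for resting lymphocyte genes 0 of 10 (0.656), and for the IL-2 and STAT5 response 0 of 18 (0.976). The interferon response had 0 of 16 (0.124), cell cycle 0 of 18 (0.838), helper T cell cytokines and regulators 0 of 6 (0.996), and inhibitory and costimulatory receptors 0 of 15 (0.438). For CD4 T cell identity 0 of 11 passed (0.21), for cholesterol synthesis 0 of 12 (0.223) and for glycolysis 0 of 11 (0.838). Marker lists of other cells also had 0 genes passing, with B cells at 0.142, myeloid cells at 0.916, dendritic cells at 0.608, NK cells at 0.996, CD8 T cells at 0.142 and erythroid cells and platelets at 0.542. Cd8a differed by 0.63 (SE 0.387) and Cd8b1 by 0.095 (SE 0.105), the chains of the CD8 coreceptor. Sex-linked genes had 0 of 3 passing (0.542). These parenthesised values are camera adjusted p. In each of these lists 0 to 2 genes had an unadjusted p under 0.05, and fry gave adjusted p from 0.735 to 0.944. Adjusted over the list alone, Flicr passed among locus neighbours, Il7r among resting genes, Cd80 among receptors and Fcmr, an IgM receptor gene of lymphocytes, among B cell markers. Other settings moved several of these camera calls, and each call they made was lost with an estimated correlation (adjusted p from 0.247 to 0.924). Without wild-type Treg replicate 1 the Treg-up signature was called downward (adjusted p = 0.00273, and 0.924 with an estimated correlation) and CD8 markers upward (0.0382). With no filter the Treg-up signature (0.00987, and 0.769 with an estimated correlation), Foxp3 locus neighbours (0.0193) and effector Treg genes (0.0193) were called downward. Without knockout Treg replicate 1, downward calls were made for Foxp3 locus neighbours (adjusted p = 0.0142), effector Treg genes (0.0216), cell cycle (0.0243) and cholesterol synthesis (0.0196), which became 0.247, 0.453, 0.247 and 0.264 with an estimated correlation. Without wild-type Treg replicate 2 the locus (0.00563), effector genes (0.0365) and dendritic cell markers (0.0365) were called downward and the interferon response upward (0.00151). Interferon (0.00771) and CD8 markers (0.0234) were called upward without knockout Treg replicate 3, and B cell markers (0.0437) without knockout Treg replicate 2. With the term for high immediate early scores the locus (0.00371) and effector genes (0.0046) were called downward and B cell markers upward (0.0317). The locus list includes Flicr, the gene knocked out. In the main fit the median log2 difference of that list was 0.0024, with 9 genes positive and 9 negative. Its downward calls therefore do not show a shift of the genes around Flicr.

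The second comparison set wild-type Tregs against wild-type Tconvs. Flicr intensity was 5.88-fold higher in Tregs, above a Tconv level not shown to exceed background (log2 difference 2.56, SE 0.155) and Foxp3 11.8-fold higher (3.56, SE 0.0933), each above both Tconv arrays in all 3 Treg arrays. No overlap between these groups was found for 4705 of 9815 genes (47.9%, where chance gives 20%). Rgs1, a regulator of G-protein signalling, was 13.2-fold higher, Lrrc32, the GARP protein that displays latent TGF-beta, 13.0-fold, Ctla4 11.4-fold and Ikzf2 8.05-fold. In the other direction Dapl1 was 14.0-fold lower, the phosphodiesterase gene Pde3b 12.3-fold and Vipr1, a receptor for vasoactive intestinal peptide, 9.15-fold. Il2ra was 27.3-fold higher, but its product CD25 was the marker used to sort the cells.

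In limma with Benjamini-Hochberg adjustment, adjusted p = 2.27e-09 for Foxp3, 9.81e-07 for Flicr, 1.44e-07 for Rgs1 and 1.74e-08 for Dapl1. Of 9815 genes 1360 passed, 742 higher and 618 lower in Tregs, and 211 of these differed at least 2-fold, 147 higher and 64 lower. Socs2, an inhibitor of cytokine signalling, rose 9.44-fold, Arhgap20 7.44-fold, Penk, which encodes proenkephalin, 6.63-fold and Klrg1, a receptor of differentiated T cells, 6.10-fold. Mctp2, Slc16a5, Pdlim4, Igfbp4, Adh1, Sgk1 and Cd40lg, the ligand of CD40, fell, with log2 differences of -2.88, -2.51, -2.49, -2.28, -2.12, -2.12 and -2.09. A second probe set of Socs2 gave a log2 difference of 1.72 and a second one of Vipr1 gave -0.89. Ppp1r3f (log2 difference 0.31, adjusted p = 0.131) and Ccdc22 (0.22, adjusted p = 0.429) did not pass in limma, and Cacna1f, below the filter, differed by -0.035. The count was 596 without Tconv replicate 1, 533 without Tconv replicate 2, 872 without wild-type Treg replicate 2, 3585 with array weights and 755 with the stress score as a covariate, an alternative chosen after seeing the data.

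**Figure D3:**
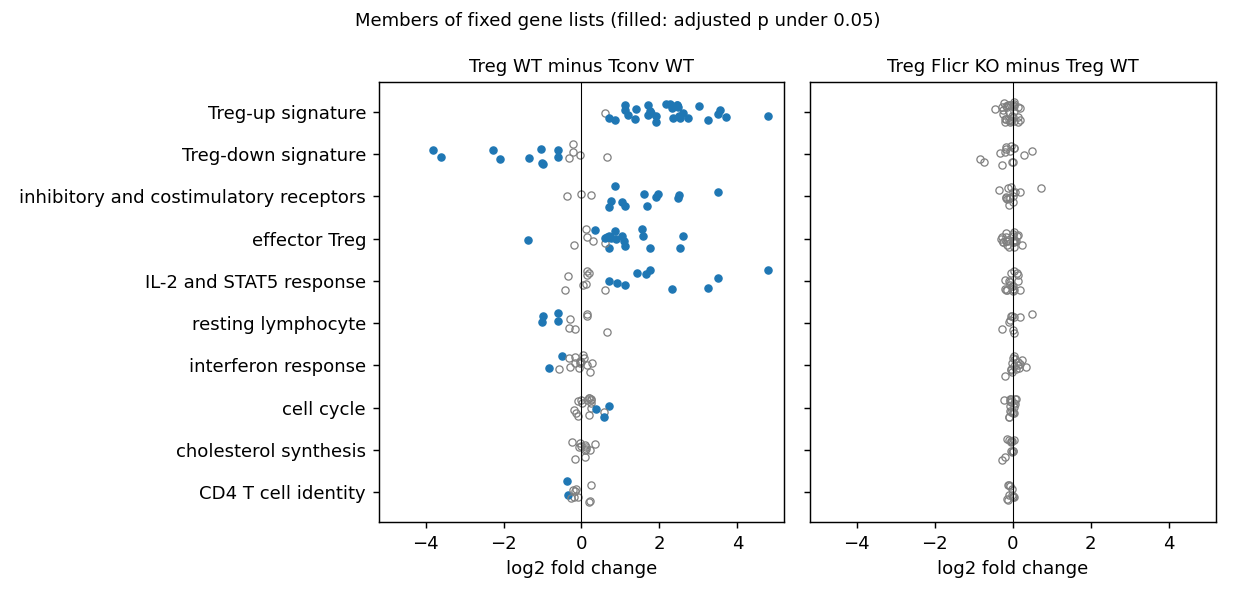
Log2 fold change of each measured member of 10 fixed gene lists, for wild-type Tregs minus Tconvs (left) and Flicr-knockout minus wild-type Tregs (right), with filled points for genes at an adjusted p under 0.05 in limma. In the left panel 30 of 31 Treg-up genes are filled, and in the right panel 0 of 31 are.

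The Treg-up signature rose in 30 of 31 measured members, with a median log2 difference of 2.27. Inhibitory and costimulatory receptors followed, with 12 of 15 members higher, among them Tnfrsf9 (4-1BB, 2.50), Tnfrsf4 (OX40, 2.48) and Cd80 (1.96, and 0.88 by a second probe set), while Cd27 and Cd28 had differences of -0.015 and 0.25 and did not pass. Of 22 effector Treg genes 16 rose, such as Itgae, the CD103 integrin chain (2.52), Gzmb, a cytotoxic granule protease (1.76), and the chemokine receptor gene Ccr6 (1.58), and Id2, a transcriptional inhibitor, fell by 1.36. Lgals1 (0.12) and Ccr4 (0.30) in that list did not pass. The IL-2 and STAT5 response had 10 of 18 members higher, with Il2rb at 2.31, and Ccnd2, a cyclin, at 0.19 without passing. Of 17 TCR and immediate early genes 6 rose, among them the phosphatase gene Dusp1 (1.88) and the transcription factors Irf4 (1.56) and Nr4a1 (1.34). The mean log2 level of that list was 8.81 and 8.76 in the Tconv arrays. Prdm1, which encodes Blimp-1, was the Treg-up member that missed the threshold (0.59, adjusted p = 0.0547 in limma).

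In camera the adjusted p was 1.83e-47 for the Treg-up signature, 7.47e-16 for the receptors, 1.09e-12 for effector genes, 1.88e-10 for the IL-2 and STAT5 response and 1.49e-06 for immediate early genes. With an estimated correlation these 5 calls were lost, at adjusted p = 0.109 for the first 4 and adjusted p = 0.152 for the last, whereas fry called all 5. With an estimated correlation and no filter the first 4 passed (adjusted p from 0.0421 to 0.0429), as did the Treg-up signature and the receptors after renewed quantile normalization (0.0278). Adjusted over the list alone, 31 Treg-up genes, 13 receptors and 18 effector genes passed upward, as did 11 genes of the IL-2 and STAT5 response and 9 immediate early genes. Many members are shared between these lists, and Il2ra is a sorted marker. The count of immediate early genes was 3 without Tconv replicate 1 and 3 without Tconv replicate 2, and adjusted over the list alone it was 5 and 4. With the stress score as a covariate Dusp1 (adjusted p = 0.364 in limma) and Gzmb (adjusted p = 0.0614) no longer passed. Dusp1 is itself a member of that score. The score was 9.17 and 9.10 in the Tconv arrays and 9.54 to 9.70 in the wild-type Treg arrays. It thus overlaps with the cell-type difference, so these losses and the count of 755 genes cannot show which differences are weak.

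The Treg-down signature fell in 10 of 15 measured members, with a median log2 difference of -0.98. Dapl1, Pde3b, Igfbp4 and Cd40lg fell most among those named, and St8sia6, a sialyltransferase (-0.23), and Bach2, a transcriptional repressor of lymphocyte differentiation (-0.32), did not pass. Of 10 resting lymphocyte genes 4 fell, namely the transcription factor Lef1 by 1.02, Il7r by 0.98, the chromatin organiser Satb1 by 0.61 and the homing receptor Ccr7 by 0.60. Bcl2, a survival factor, and Foxo1, a transcription factor of quiescent T cells, had differences of 0.13 each. Camera gave adjusted p = 1.84e-12 for the Treg-down signature and 0.00719 for resting genes, which with an estimated correlation became adjusted p = 0.109 and adjusted p = 0.179. Fry called both lists downward (adjusted p = 0.000179 and 0.00108). The Treg-down signature passed with an estimated correlation with no filter (adjusted p = 0.0421) and after renewed quantile normalization (0.0278). Adjusted over the list alone, 11 Treg-down genes passed downward and 1 upward, and 6 resting genes passed downward and 1 upward. No Treg-down gene passed upward without Tconv replicate 1, and no resting gene without Tconv replicate 1 or wild-type Treg replicate 2. Ccr7 did not pass without Tconv replicate 1 (adjusted p = 0.0588 in limma).

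At the Foxp3 locus 4 of 18 measured genes rose, namely Foxp3, Flicr, the erythroid transcription factor gene Gata1 (1.02) and the synaptic vesicle gene Syp (0.48). Pqbp1, a splicing gene chosen after its value was seen, fell by 0.32 (adjusted p = 0.0497 in limma), and Plp2 (0.29) and Was (-0.17) did not pass. With either Tconv array left out, or wild-type Treg replicate 2 or 3, 0 genes of the list passed downward. Camera gave the list an adjusted p of 0.0246, which became adjusted p = 0.519 with an estimated correlation, while fry gave 0.00335. Without wild-type Treg replicate 1 the camera call ended (adjusted p = 0.0502). Both measured B cell markers rose, with Cd79b, a chain of the B cell receptor complex, at 1.20 and Fcmr at 0.56. The adjusted p of this list was 0.00759 in camera, 0.109 with an estimated correlation and 0.000622 by fry. With no filter, which adds other B cell genes such as Cd79a (0.16) and Ms4a1 (-0.022), 2 of 13 genes were higher. The camera call then ended at an adjusted p of 0.259, while fry gave 0.0315. Without Tconv replicate 1 Syp (adjusted p = 0.23 in limma) and Fcmr (0.0751) did not pass, and without Tconv replicate 2 the values were 0.109 and 0.202. By the same test Syp did not pass without wild-type Treg replicate 2 (adjusted p = 0.0617 in limma) or replicate 3 (0.0855).

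The other 13 lists were not called by camera, whose adjusted p follows each in parentheses. In cell cycle 3 of 18 genes rose, Mki67, a marker of dividing cells (0.70), Ccnb2, a mitotic cyclin (0.58), and Mcm5, a helicase subunit (0.36), while Pcna at -0.091 and Mcm4 at -0.10 did not pass (adjusted p = 0.0535). In the interferon response 2 of 16 fell, the antiviral genes Oasl2 by 0.83 and Ddx58 by 0.49, and Trim30a differed by 0.23 without passing (0.247). Among helper T cell cytokines and regulators 2 of 6 rose, Tnf by 0.69 and the follicular homing receptor gene Cxcr5 by 0.51, and Gata3 differed by 0.35 without passing (0.268). In CD4 T cell identity 2 of 11 fell, Thy1 by 0.38 and the CD3 chain gene Cd3g by 0.35 (0.247). In glycolysis the glucose transporter gene Slc2a3 rose by 1.52 and Aldoa, aldolase A, fell by 0.43, of 11 measured (0.436). Cholesterol synthesis had 0 of 12 passing (0.635), and heat shock and dissociation stress 0 of 8 (0.499). Each of these last lists had 2 genes at an unadjusted p under 0.05, and fry gave adjusted p of 0.627 and 0.522. With the stress score as a covariate, Mki67 (0.083, adjusted p = 0.858 in limma), Ccnb2 (0.22, 0.57) and Mcm5 (0.28, 0.329) did not pass. Nor did Ddx58, Tnf, Cxcr5, Thy1, Cd3g and Aldoa, though that score itself differed between the cell types. Many of the smaller differences in these lists also rested on single arrays. Without Tconv replicate 1, Mki67 (adjusted p = 0.0834 in limma), Mcm5 (0.184), Oasl2 (0.0547), Ddx58 (0.0893), Tnf (0.161), Cxcr5 (0.174), Thy1 (0.131), Cd3g (0.17) and Aldoa (0.212) did not pass. Without Tconv replicate 2, Mki67 (adjusted p = 0.2 in limma), Ccnb2 (0.262), Mcm5 (0.168), Oasl2 (0.103), Tnf (0.173), Cxcr5 (0.286), Thy1 (0.291), Cd3g (0.219) and Aldoa (0.14) did not. Leaving out wild-type Treg replicate 1 ended the calls of Cxcr5 (adjusted p = 0.0735 in limma) and Cd3g (0.0663). With replicate 2 of the wild-type Tregs left out, Mki67 (adjusted p = 0.0571 in limma), Ccnb2 (0.0603), Tnf (0.0946), Thy1 (0.123), Cd3g (0.0575) and Aldoa (0.113) did not pass, and with replicate 3 left out Mcm5 (0.0855), Tnf (0.0582), Cxcr5 (0.129), Thy1 (0.0799) and Cd3g (0.0555) did not. Slc2a3 passed in each of these fits. Camera called the cell cycle list upward with no filter (adjusted p = 9.64e-05), with only the groups compared (0.0294), with arrays centred (0.0425), without Tconv replicate 1 (0.0429) and without wild-type Treg replicate 3 (0.0228). Each of these calls was lost with an estimated correlation (adjusted p from 0.237 to 0.578). Without wild-type Treg replicate 1, cholesterol synthesis had 1 member higher, and heat shock and dissociation stress 1 higher and 1 lower.

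Markers of other cells differed in both directions. Among myeloid genes the protease gene Ctss rose by 0.72, as 1 of 2 measured (camera adjusted p = 0.268), and among dendritic cell genes Cd74, the invariant chain of antigen presentation, rose by 0.72, as 1 of 2 (0.225). Of 3 NK cell genes Prf1, perforin, fell by 1.24 (0.268). With no filter 3 of 10 NK cell genes fell, with the NK receptor genes Klrd1 (-1.61) and Klrc1 (-0.61), chosen after their values were seen, beside Prf1. Camera then called the list downward (adjusted p = 0.000935), which became adjusted p = 0.104 with an estimated correlation. Of the CD8 coreceptor chains Cd8b1 fell by 0.62, whereas Cd8a differed by 0.30 without passing (0.308). Cd8a was at 8.07 in wild-type Treg replicate 1, at 6.85 and 6.78 in replicates 2 and 3, and at 6.85 and 7.01 in the Tconvs. Without wild-type Treg replicate 1 both chains had negative differences, with a median of -0.39. Erythroid and platelet markers had 0 of 2 passing (0.586) and sex-linked genes 0 of 3 (0.635), with 0 genes at an unadjusted p under 0.05 and fry adjusted p of 0.227 and 0.676. By fry the myeloid (adjusted p = 0.022) and NK cell lists (0.0496) were called. Camera with an estimated correlation called neither (adjusted p = 0.519 for each). With no filter fry lost the myeloid list (adjusted p = 0.731) and kept the NK cell list (0.00303). The fry call of NK cell genes was lost without wild-type Treg replicate 1 (adjusted p = 0.121) or 2 (0.13). Centring the arrays ended both fry calls (adjusted p = 0.0717 for each). Cd74 (adjusted p = 0.14 in limma) and Cd8b1 (0.0692) did not pass without Tconv replicate 1, nor Cd74 (0.0896) and Ctss (0.162) without Tconv replicate 2.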

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

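The test of CD8 T cells was chosen only after the result was seen. Data outside the comparisons held differences of their own. Among 751 probe sets that name several genes, 33 were higher and 41 lower in wild-type Tregs than in Tconvs in limma with Benjamini-Hochberg adjustment, and among 941 with no gene listed, 61 were higher and 49 lower. Between genotypes 0 of either kind passed in limma, with 11 and 14 at an unadjusted p under 0.05.

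The 6 Treg arrays can be divided into groups of 3 in 10 ways, too few for a share under 0.05. The division by genotype called 1 gene, 2 of the 10 divisions called at least as many, and the highest other called 1625. That other one set knockout replicates 1 and 2 with wild-type replicate 1, and it points to a structure of the Treg samples beside their genotype. The remaining 8 called 0 genes, with 0.846% to 13.3% of genes at an unadjusted p under 0.05.

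Immediate early transcripts varied along this structure. Fos had log2 levels of 8.63, 8.20 and 6.92 in knockout Tregs and 8.02, 6.99 and 6.97 in wild-type Tregs, and the list's mean ranged over 0.55. Uneven distributions left by the authors' normalization are argued against, since 97.1% of the range stayed after renewed quantile normalization. CD8 T cells cannot be told apart from other sources: Cd8a ranged more widely than Cd8b1 by 1.27 on the log2 scale, but the lowest Cd8b1 level lies 1.21 above the lowest Cd8a level and would hide a small share, and the sort excluded CD8. Handling on the day of the sort, activation of the mice's T cells and a contribution of Flicr genotype stay open and untested, as the labels give no day or batch.

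Fewer genes than chance gives had a small p between genotypes, 2.27% against 5%, but this rested on single arrays, with 9.88% without wild-type replicate 1, 8.36% without knockout replicate 3, 11.3% with array weights, and 1.19% to 1.37% without knockout replicate 2, wild-type replicate 2 or wild-type replicate 3. Divisions of the Treg arrays that called 0 genes gave shares from 0.846% to 13.3%, so 2.27% lies within their range. A candidate explanation for a low share was that stress transcripts vary across genotypes and widen the residual spread. With the stress score as a covariate the share was 2.28%, and with a term for the 3 Treg arrays with high immediate early scores, chosen after they were seen, it was 3.14%, both short of the rise to 5% that this needs. Both argue against the explanation, though the score itself was higher on average in knockout Tregs, so a covariate cannot cleanly remove it. Leaving out wild-type replicate 1 or knockout replicate 3 does bring such a rise. Each of these arrays sat apart from the others of its genotype in the division that called 1625 genes. Once either is left out, that division follows genotype more closely. The rise thus cannot tell the explanation from this alignment, and the explanation stays open. No biological explanation was tested for this share.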

How the results depend on the processing

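Tests with the stress score, with a term for 3 Treg arrays with high immediate early scores, and the lists under both renewed scalings were chosen after the data were seen. Flicr passed between genotypes under every alternative run (log2 difference -2.61 to -2.31) and Foxp3 under none (0.055 to 0.16). The genes called between genotypes numbered 1, as against 4 with array weights, 9 with the high-score term, and 1 to 5 when single arrays were left out. The lists called numbered 3, as against 0 with an estimated correlation, 0 by fry, 6 with no filter, 6 with the high-score term, and 3 to 7 when single arrays were left out. Between Tregs and Tconvs 1360 genes passed, as against 3585 with array weights, 755 with the stress score, 628 with a 1.5-fold minimum, and 533 to 1361 when single arrays were left out. A Tconv array left alone was assumed to vary like the other groups. With array weights the wild-type Treg mean rested mostly on replicate 2 (weight 4.50). The lists called between Tregs and Tconvs numbered 9, as against 0 with an estimated correlation, 11 by fry, and 8 to 10 when single Treg arrays were left out. The 1.5-fold minimum lowers a count by construction; for the other settings the cause was not tested. Between genotypes, differences that did not pass changed sign for Ppp1r3f (-0.011), Ccdc22 (-0.13) and Il2ra (0.14) with the stress score, for Il2ra (0.049) with the high-score term, and for Il2ra when single arrays were left out (-0.16 to 0.018, positive without knockout replicate 2, and at 0.017 without wild-type replicate 3). Between Tregs and Tconvs Ccdc22 changed sign with the stress score (-0.34). The calls of Ccr7, Syp, Fcmr and Cd74 were lost with that score (adjusted p = 0.249, 0.32, 0.59 and 0.141 in limma). Background was not measured, so these arrays do not show whether dim transcripts such as Cacna1f were detected.

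The labels do not say whether samples of the same replicate number belong together. Residuals of knockout and wild-type arrays of the same number correlated across genes at 0.148, -0.323 and 0.456. Of the 3 knockout arrays 1 correlated best with its own number. With so few arrays, whose residuals within a group depend on each other, this neither shows nor excludes pairing. With the replicate number as a block 9 genes passed between genotypes (Flicr, Igfbp4, Cxcr4, Hsph1, Dapl1, Nrn1, Ddit4, Cd80 and Dnajb1). Between Tregs and Tconvs 1569 passed, of which 1242 were among the 1360. With the block camera called 4 lists between genotypes and 10 between Tregs and Tconvs. Among the 10 was cell cycle (adjusted p = 0.0131, and 0.463 with an estimated correlation). The cause of these changes was not tested.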

Other observations

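Of 8 measured guanylate-binding proteins, interferon-inducible GTPases of cell-autonomous defence, 5 were higher in wild-type Tregs than in Tconvs. The family was chosen only after its values were seen, as was its test, and no list test was run on it. Gbp3 rose 4.10-fold (adjusted p = 1.82e-07 in limma with Benjamini-Hochberg adjustment), Gbp2b 3.91-fold, Gbp5 2.99-fold and Gbp7 2.32-fold, each higher in all 3 Treg arrays than in both Tconv arrays. Such a lack of overlap was found for 47.9% of all genes in this comparison. Gbp8 rose by 0.35 on the log2 scale (adjusted p = 0.0343 in limma), a call lost without Tconv replicate 1 (0.321), Tconv replicate 2 (0.0953), wild-type Treg replicate 2 (0.13) or wild-type Treg replicate 3 (0.0855). The other 3, Gbp9, Gbp4 and Gbp11, had differences of 0.39, 0.25 and 0.20 and did not pass (adjusted p = 0.0894, 0.189 and 0.344), though Gbp9 passed without wild-type Treg replicate 1 (0.00402). Signs were the same for all 8 after renewed quantile normalization and after centring. Between genotypes 0 of the 8 passed in limma, with Gbp2b at -0.28.

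The hypothesis that these genes are part of a general interferon response in Tregs was tested on the fixed interferon list, which holds mostly genes of the type I response. Its 16 measured members had a median log2 difference of -0.043 (quartiles -0.30 and 0.050), with 11 negative, against 0.80 for the guanylate-binding proteins. This argues against a general response of that kind. A response limited to interferon-gamma was not tested separately, since this list was not made to tell it from a type I response.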
